A study of Mus musculus with 6 samples.

How the data were processed

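The series compared freshly isolated thymocytes of 6 mice, 3 with a T-cell-directed deletion of Klf4 and 3 controls without the Cre transgene. Per the labels, all mice carried 2 floxed Klf4 alleles, came from a C57/BL6 background and were 8 to 10 weeks old. The knockout mice also carried Cre recombinase under the Cd4 promoter, which is switched on at the double-positive stage of thymocyte development. Per the labels' protocols, cells were enriched by their CD4 protein with 1 of 2 commercial kits to a purity above 94%, which takes both double-positive (DP) and CD4 single-positive (SP4) thymocytes. Total RNA was amplified, labelled with biotin and hybridised to Illumina MouseRef-8 v2 bead arrays, on which each probe reports 1 colour. The labels do not say which kit was used for which mouse, nor the sex of any mouse.

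The deposited values are scores: each array was standardised by the authors to a mean of 0 and an SD of 1 over its 25697 probes, as the values themselves show. GenomeStudio 2010.1 is named in the submitters' processing notes, with no role. Background correction and any step before the standardisation are not given in the sources used here. It is unknown whether intensities or their logarithms were standardised, and the base of any logarithm, so differences are given in z units (SDs of one array's probes) or as percentiles of an array, and no fold change is stated. A z unit need not mean the same change at low and at high signal. The table was used without detection p-values, so no probe was called as above or below background. The column medians were -0.493, -0.489 and -0.49 for knockouts 1 to 3 and -0.488, -0.491 and -0.487 for controls 1 to 3. The lowest and highest values over all arrays lay near -1.03 and 5.02. The table held 0 columns of other samples. The number of arrays, 3 per genotype, limits the precision.

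Probe names came from GEO's platform annotation, updated through gene identifiers to the symbols of the RefSeq annotation of mouse assembly GRCm38.p6. 23978 probes had 1 gene symbol, 0 had several and 1719 had none and stayed unnamed here. 23962 identifiers were found in the RefSeq table and 16 were not. The assembly served for names and for the order of neighbouring genes, and no coordinates are given.

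Before the data were examined, the test, the filter, the gene lists, the alternatives and the rule for named genes were fixed. Quantile normalization between arrays was to be used where the quartiles of the arrays differed by more than 5% of the interquartile range. The largest gap was 6.93%, so quantile normalization was applied to the deposited scores. That gap was in the upper quartile, which was 0.517 in control 3 and 0.436 to 0.477 in the other mice. The highest score of control 3 was 4.52, against 4.77 to 5.02 in the other mice. Another sentence of the same plan said that values on a z scale would be used as deposited, and those values are therefore given as an alternative. Probes whose mean over the 6 arrays lay under the 40th percentile were left out as dim, which removed 10279 probes and left 15418, with 10399 gene symbols. The planned test had been written for log2 values and was applied to the z scale.

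Differences between genotypes were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), and p-values were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. The standard error (SE) of a difference is limma's moderated one. Adjusted p-values of probes and genes are limma's, and those of gene lists are from camera, described next. Those of stretches of neighbouring genes are from shuffled gene order. 25 gene lists with 702 entries, of which 626 were on the array, were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe per gene (the one with the highest mean) and at least 5 genes per list, which left 24 lists. The list of Y-linked genes and Xist, with 4 genes, was too short to test. An estimated correlation per list was the alternative. It rests on 4 residual degrees of freedom, so a list that does not pass with it may still be shifted. Within each list the members were also adjusted over the list alone. List medians of single mice take all genes of a list on the array, dim ones included. Median differences between the genotypes take the tested genes only. The replicates are separate mice, as stated in the series' design.

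Genes were named by a fixed rule. Klf4 was always given. With 1 probe per symbol, the 12 largest rises and 12 largest falls past the threshold were to be named, filled up where fewer passed by the genes with the smallest p, given as values that did not pass. Up to 4 genes per list followed by the same order, and Cdkn1b, Cdkn1a, Cd4, Cd8a, Rag1, Klf2, S1pr1, Ccr7, Il7r, Cd69 and Il17a wherever measured. One further gene of that rule is not reported here. Cd8a and S1pr1 had dim probes and were taken from a fit on all probes. The text names part of the genes the rule gives, and the alternatives were run on each of them, except where an alternative's filter removed its probe.

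The code was tested on simulated data with the means and spreads of the 15418 probes. Of 200 changed probes, limma called 55.2% of those changed by 0.25 z units, 85.1% of those changed by 0.5 and 98.5% of those changed by 1, with 10 unchanged probes among 169 calls. In 20 simulations without change at most 1 probe and 0 lists were called. The simulated probes were independent of each other, so they do not check the list test for genes that vary together. The recovered shares depend on how many probes change.

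Alternatives were no filter and a filter at the 60th percentile, the deposited scores, median centring, eBayes without trend or with trend and robust, array weights, the replicate number as a block, each of the 6 mice left out in turn, 1 probe per gene, an unequal-variance test per probe, an adjusted p under 0.1, and for lists an estimated correlation and camera with ranks. Other splits of the 6 mice into 3 and 3 were fitted in the same way. For each split, the 100 genes with the smallest p were placed in genome order, and the largest number in a stretch of 100 consecutive tested genes was compared with 10000 shuffles of gene order. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.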

Results

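Transcript levels were measured in DP and SP4 thymocytes from 3 mice with a CD4-Cre-driven deletion of Klf4 and 3 floxed controls without Cre. KLF4 is a zinc-finger transcription factor that restrains the cell cycle in several tissues, and the series asks how its loss alters T cells. Each mouse gave 1 array of 25697 probes. Over the probes tested, arrays correlated pairwise with Pearson r between 0.992 and 0.9963, across probes, which are not independent replicates. The first principal component took 30.2% of the variance and the second 25.5%. On the first, knockouts 1 to 3 stood at 8.51, 4.47 and -0.39, above controls 1 to 3 at -3.32, -3.05 and -6.22. Control 3 stood at 7.82 on the second component, with knockout 1 next at 4.92 and the other 4 mice between -4.09 and -2.12.

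Klf4, the deleted gene, was lower in the knockout mice on 2 of its 3 probes. On probe ILMN_1241903 the control mice read 0.05, 0.109 and -0.145 z units and the knockout mice -0.555, -0.758 and -0.696. The group means were 0.0045 ± 0.133 (SD, n = 3) and -0.67 ± 0.104 (SD, n = 3), a difference of -0.674 (SE 0.0679, adjusted p = 0.00265), and the mean percentile within the array went from 66.7 to 28.2. On probe ILMN_1221264 the means were -0.311 ± 0.104 and -0.687 ± 0.0444 (SD, n = 3 each), a difference of -0.376 (SE 0.052, adjusted p = 0.046), with percentiles of 58.6 and 27.1. On both probes all 3 knockout values lay below all 3 control values. The third probe, ILMN_2999439, read 0.479 ± 0.159 in control and 0.516 ± 0.189 in knockout mice (SD, n = 3 each), a difference of 0.0367 (adjusted p = 0.944), and its sign turned when knockout 2 or control 3 was left out. Where each probe lies relative to the deleted part of the gene is not known here, and a probe outside that part does not check the deletion. The call on ILMN_1221264 was lost in the fit without a trend in the variance (adjusted p = 0.141) and in each fit that left out 1 mouse other than control 3 (adjusted p up to 0.264).

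**Figure D1:**
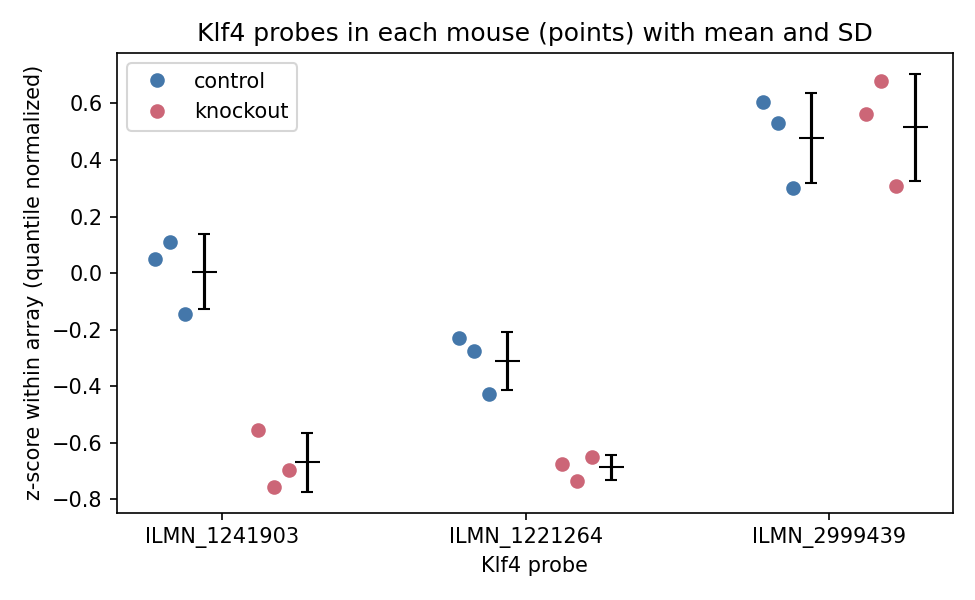
Klf4 z-scores (y axis, quantile normalized, no unit beyond SDs of an array) on the 3 Klf4 probes (x axis), with a point per mouse and the mean and SD of each genotype in black. Knockout mice lie below all controls on ILMN_1241903 and ILMN_1221264, with means of -0.67 and -0.687, and overlap the controls on ILMN_2999439.

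Beyond Klf4, no probe passed the threshold between the genotypes. Of 15418 probes, limma called 0 higher and 2 lower in the knockout, and both calls were the Klf4 probes, which is 1 gene symbol. At an unadjusted p under 0.05 there were 627 higher and 733 lower probes, 1360 in all or 8.82%, where 5% (771 probes) would be expected by chance. The 2 groups did not overlap in 14.07% of probes, against 10% by chance. Differences of more than 0.5 z units were found in 14 probes. Among these were probes of Xist (-0.873 and -0.597) and Eif2s3y (0.804), genes of the sex chromosomes in which control 3 stood apart. Without control 3 the Eif2s3y difference was -0.096. The 95% interval of the difference lay within 0.5 either side of 0 for 99.68% of the probes, with a median half-width of 0.114. This bound does not mark a change as small, since Klf4 probe ILMN_1221264, at -0.376, went from percentile 58.6 to 27.1. The counts depended on the setting, with 0 lower at the stricter filter, which removes both Klf4 probes, and 0 higher and 0 lower with the unequal-variance test per probe. Without knockout 1 the lower count was 4, without knockout 3, control 1 or control 2 it was 1, and without control 3 the higher count was 1.

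The genes with the smallest p in each direction did not pass and are given as values. On the higher side these were Calr, which encodes the endoplasmic reticulum chaperone calreticulin, at 0.331 (SE 0.05, adjusted p = 0.0791), Cirbp, an RNA-binding protein induced by cold, at 0.337 (SE 0.059, adjusted p = 0.179), and Rbl2, which encodes the pocket protein p130, at 0.406 (SE 0.077, adjusted p = 0.217). Fndc10, Adgre5, the class Ib gene H2-Q8, Cyp4f13, the peptide transporter gene Tap2, Pbxip1, the DNA polymerase gene Polm, the transcription factor Bach1 and Entpd4 followed, with differences from 0.193 for Tap2 to 0.501 for Bach1. A second Rbl2 probe differed by 0.0384. With robust variance Calr was the 1 probe called higher (adjusted p = 0.0441), and with the replicate number as a block Bach1 passed (adjusted p = 0.0134). On the lower side the difference largest in size was that of Slc15a2, a transporter of small peptides, at -1.486 (SE 0.252, adjusted p = 0.151), with a control mean of 1.422 ± 0.373 and a knockout mean of -0.064 ± 0.681 (SD, n = 3 each). Its knockout values of -0.113, 0.639 and -0.72 were spread widely, and without knockout 2 it passed at an adjusted p of 0.00398. Kansl1l differed by -0.884 (SE 0.182, adjusted p = 0.256) and passed without knockout 1 (adjusted p = 0.00197). Dynll1, a dynein light chain, differed by -0.32, the kinase gene Stk17b by -0.323 and Ogt, which encodes the O-GlcNAc transferase, by -0.31, where its other tested probes gave -0.0998 and -0.122. Nptn, Zfp868, the splicing factor gene Srsf3, the Notch target Hey1, Ube2d3, Csgalnact1 and Trappc13 had differences between -0.367 and -0.224.

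Genes that govern division were followed because of the known role of KLF4 as a brake on the cell cycle. Among 19 inhibitors of cyclin-dependent kinases and other antiproliferative genes, 8 differences were above 0 and 11 below, with a median of -0.032 and a mean of 0.028, which differ in sign (camera adjusted p = 0.845). Over all probes 0 of them passed. Adjusted over the list alone, Rbl2 and Cdkn1b, which encodes the kinase inhibitor p27, were higher and the retinoblastoma gene Rb1 was lower. A second tested Rbl2 probe differed by 0.0384. Rbl2 was also among leading genes crowded into a stretch of neighbours in a split that did not follow genotype (adjusted p = 0.047 from the shuffles). Cdkn1b read 1.069 ± 0.122 in control and 1.388 ± 0.185 in knockout mice (SD, n = 3 each), a difference of 0.319 (SE 0.085, adjusted p = 0.349 over all probes), and a second tested probe gave 0.142. Cdkn1a, the p21 gene, differed by 0.055 (adjusted p = 0.841), and by 0.009 without control 3, 0.018 without knockout 1 and 0.117 without control 1. The list of G1/S and DNA replication genes was higher as a group, with 29 of 38 differences above 0 and a median of 0.045 (camera adjusted p = 0.00108), though 0 members passed over all probes or adjusted over the list alone. With an estimated correlation the list's adjusted p = 0.824. Splits of the mice that did not follow genotype called 1 to 8 lists at the preset correlation. Mcm7 and Mcm3, subunits of the replicative helicase, differed by 0.179 and 0.191, and Cdc6, which loads it, by 0.167. Control 3 had the lowest median of this list, 1.235 against 1.338 to 1.444 in the other mice, and without control 3 the median was 0.016 (adjusted p = 0.37). The call was also lost without knockout 1, with a median of 0.011 (adjusted p = 0.206), and with array weights, with one of 0.029 (adjusted p = 0.0747). Without knockout 3 or control 2 it passed with larger medians of 0.072 and 0.068. In the G2/M and mitosis list 23 of 34 differences were below 0, with a median of -0.029 (adjusted p = 0.234). It passed in the lower direction without control 3 (median -0.055, adjusted p = 0.000671), without knockout 1 (median -0.072, adjusted p = 0.00121) and with array weights (median -0.051, adjusted p = 0.00486). It lay nearer 0 without knockout 2 (median -0.005, adjusted p = 0.746), knockout 3 (median -0.012, adjusted p = 0.62) or control 2 (median -0.015, adjusted p = 0.789). Nusap1, which binds spindle microtubules, differed by -0.14 and Pttg1, which encodes securin, by 0.146 (0.092 without control 3).

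The markers of thymocyte stages gave 1 list past the threshold. The DP thymocyte programme was lower as a group, with 11 of 15 differences below 0 and a median of -0.053 (camera adjusted p = 0.00705), and 0 members passed over all probes or adjusted over the list alone. With an estimated correlation its adjusted p = 0.824. Themis, needed for positive selection, differed by -0.239 (SE 0.072), Dntt, which encodes terminal deoxynucleotidyl transferase, by -0.137 (SE 0.043) and St6gal1 by -0.19 (SE 0.072). Without control 3 Themis differed by -0.158, and without knockout 1 St6gal1 differed by -0.121. Rag1, a recombinase subunit, differed by -0.077 (adjusted p = 0.644). Control 3 had the highest median of this list, 2.094 against 1.79 to 1.952 in the other mice. Without control 3 the median was -0.032 (adjusted p = 0.641), and without control 1 it was -0.084 (adjusted p = 0.000607). The call was also lost with the deposited scores (median -0.022), median centring (-0.02) and array weights (-0.049). The mature SP4 programme had a median of 0.003 over 23 genes (adjusted p = 0.387; -0.008 to 0.039 without 1 mouse), with the survival gene Bcl2 at 0.183 and Foxp1 at 0.205, while the other tested Bcl2 probes gave -0.0061 to 0.0792. Cd4 differed by 0.02 (adjusted p = 0.961), Klf2, a transcription factor of thymic emigration, by 0.058, Il7r by 0.054 and Ccr7 by -0.139 (adjusted p = 0.597; -0.087 without knockout 2 and -0.217 without knockout 3). Cd8a and S1pr1 had dim probes and differed by -0.013 and -0.019. The signs of Cd4, Klf2, Il7r, Cd8a and S1pr1 turned when single mice were left out.

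Genes downstream of the T-cell receptor did not pass as groups over all 6 mice. The 27 genes of the signal response and positive selection list had a median of -0.011 (adjusted p = 0.708) and the 20 genes of the receptor complex and proximal signalling list one of -0.018 (adjusted p = 0.169). The latter list passed in the lower direction without knockout 3 (median -0.043, adjusted p = 0.0496), without control 1 (median -0.03, adjusted p = 0.0299) and without control 2 (median -0.038, adjusted p = 0.04). Its median was -0.011 without knockout 1 (adjusted p = 0.431) and without control 3 (adjusted p = 0.91), -0.029 without knockout 2 (adjusted p = 0.302), 0.007 with the deposited scores and 0.009 with median centring. The costimulatory receptor gene Cd28 differed by 0.158 (SE 0.046; its other tested probes gave 0.109 and 0.0197), Cd53 by -0.228 (SE 0.073), Id3 by -0.18 (SE 0.078), and the early activation marker Cd69 by -0.122 (SE 0.096, adjusted p = 0.744). Without knockout 1 or control 2 the Cd69 difference was -0.015 and -0.042, and without knockout 2 or control 3 it was -0.228 and -0.221. Id3 differed by -0.117 without knockout 1 and by -0.111 without control 1. Malt1, a paracaspase that signals to NF-kappaB, differed by -0.159 (SE 0.059).

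Among effector programmes, the Treg list was higher as a group at the preset correlation. Of its 14 genes 12 differences were above 0, with a median of 0.072 (camera adjusted p = 0.00108). With an estimated correlation its adjusted p = 0.393. Over all probes 0 members passed, and adjusted over the list alone 3 were higher: Foxp3, the lineage factor of regulatory T cells, at 0.207 (SE 0.051), the integrin gene Itgae at 0.189 (SE 0.052) and the costimulatory receptor gene Tnfrsf4 at 0.187 (SE 0.061). The other 2 tested Foxp3 probes differed by 0.0661 and 0.162 and the other 4 tested Itgae probes by 0.0408 to 0.124. Itgae was also on the list of CD8 SP, NK and gamma-delta T markers, and Tnfrsf4 on that of signal response and positive selection. With the deposited scores the list passed with a smaller median of 0.046 (adjusted p = 0.0148). The list median was 0.324 to 0.338 in the knockout mice and 0.17 to 0.202 in the controls, so the groups did not overlap. This was not particular to the Treg list. Medians of the G1/S, interferon-stimulated, Th17 and DN lists did not overlap either, each higher in the knockout mice. For the DN list, the median difference over tested genes was nevertheless -0.051. By chance 10% of comparisons of 3 against 3 do not overlap. The Th17 programme had a median of 0.04 over 17 genes (adjusted p = 0.238), and without control 3 it passed in the higher direction (adjusted p = 0.0301). Adjusted over the list alone, the chemokine receptor gene Ccr6 was higher at 0.242 (SE 0.059, adjusted p = 0.325 over all probes), and a second tested probe gave 0.0976. Il17a itself differed by 0.04 (SE 0.05, adjusted p = 0.853), and its sign turned without knockout 1. The other KLF genes, 13 on the list including the unaffected Klf4 probe, had a median of 0.032 (adjusted p = 0.781). Klf3 was lower adjusted over the list alone, by -0.304 (SE 0.085, adjusted p = 0.372 over all probes), and Klf13 differed by 0.156. Without control 3 the Klf3 difference was -0.185, and without knockout 1 that of Klf13 was 0.082.

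At the preset correlation the interferon-stimulated genes were higher and the stress genes lower as groups. Of 34 interferon-stimulated genes 28 differences were above 0, with a median of 0.071 (camera adjusted p = 0.000208). With an estimated correlation the adjusted p = 0.813. Ifit3 differed by 0.23 (SE 0.068; its other tested probes gave 0.152 and 0.0418), Ddx58, which encodes the RNA sensor RIG-I, by 0.171 (SE 0.051), Bst2, which tethers virions, by 0.291 (SE 0.091) and the kinase gene Eif2ak2 by 0.148 (SE 0.05). Control 3 had the lowest median of this list, 0.354 against 0.481 to 0.609, and without control 3 the median was 0.029 (adjusted p = 0.0705). Without knockout 3 it passed with a median of 0.044 (adjusted p = 0.0271). Of 23 genes of tissue dissociation and the immediate early response 20 differences were below 0, with a median of -0.075 (camera adjusted p = 0.000371). With an estimated correlation the adjusted p = 0.813. The chaperone gene Hsp90aa1 differed by -0.161 (SE 0.047), Atf3 by -0.111 (SE 0.039), Ier2 by -0.167 (SE 0.065) and the phosphatase gene Dusp1 by -0.139 (SE 0.055). Ier2 differed by -0.111 without knockout 3 and by -0.107 without control 3, and Dusp1 by -0.081 without knockout 1. This list also responds to how cells are handled, and its median was lowest in control 3, at 0.897 against 1.045 to 1.291 in the other mice. Its call was lost without knockout 3 (median -0.067, adjusted p = 0.0878) and without control 2 (median -0.062, adjusted p = 0.0553), and without knockout 2 the median was -0.119 (adjusted p = 6.63e-08). In these 2 lists 0 genes passed over all probes or adjusted over the list alone.

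**Figure D2:**
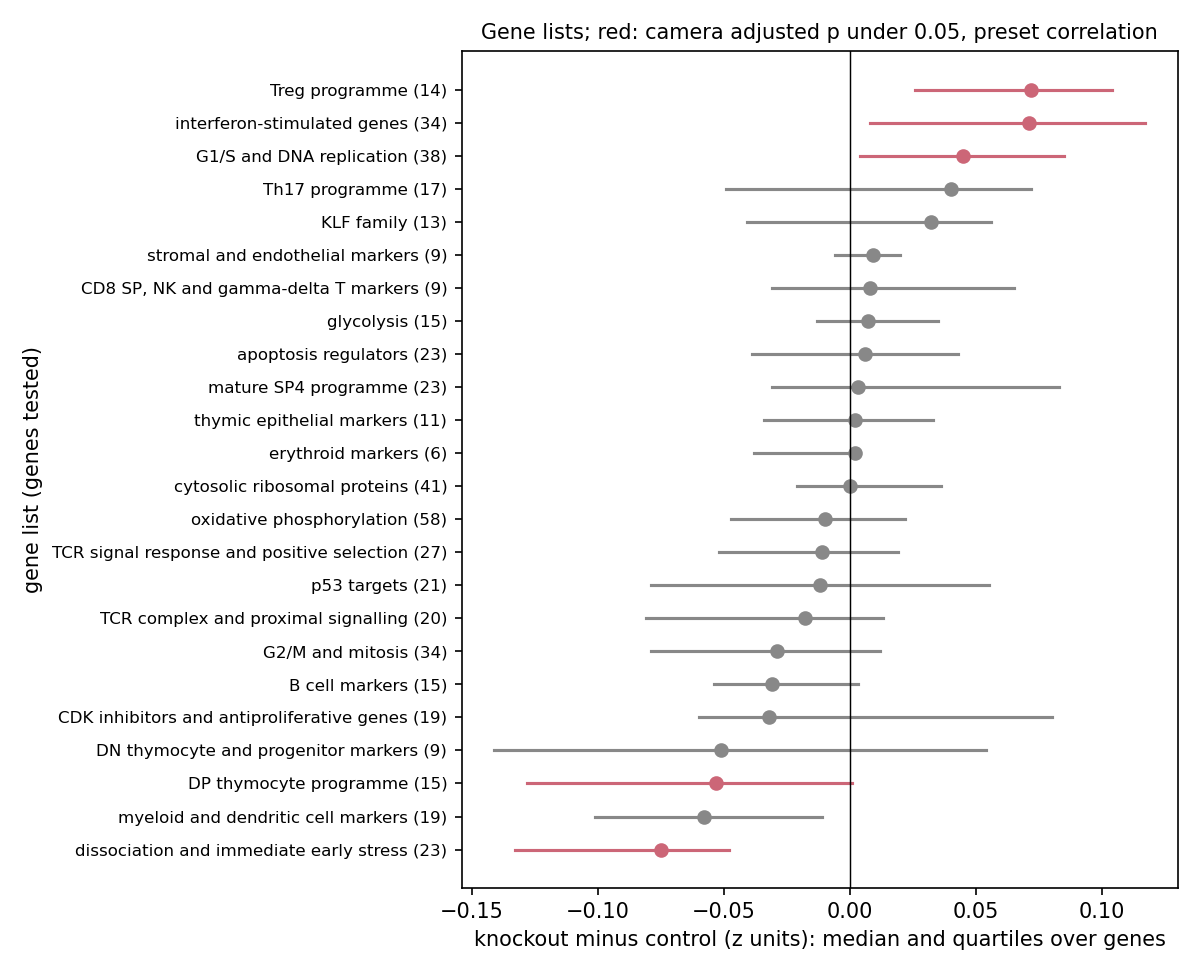
Median difference between knockout and control mice in z units (x axis; points) with the quartiles over the genes of each list (lines) for the 24 lists tested (y axis, number of genes tested in brackets), red where camera's adjusted p was under 0.05 at the preset correlation. The Treg and interferon-stimulated lists lie highest, at 0.072 and 0.071, and the stress list lowest, at -0.075.

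Lists of survival and metabolism did not pass over all 6 mice. The p53 targets had a median of -0.012 over 21 genes (adjusted p = 0.708; -0.041 to 0.016 without 1 mouse), with the death receptor gene Tnfrsf10b higher adjusted over the list alone at 0.223 and Trp53inp1 at -0.15. Apoptosis regulators had a median of 0.006 over 23 genes (adjusted p = 0.708). Cytosolic ribosomal proteins (41 genes), glycolysis (15 genes) and oxidative phosphorylation (58 genes) had medians of 0, 0.007 and -0.01, each with an adjusted p of 0.708. The ribosomal list passed in the higher direction with the deposited scores (median 0.085, adjusted p = 8.67e-05) and with median centring (median 0.087, adjusted p = 9.52e-05), and oxidative phosphorylation passed in the lower direction without control 3 (median -0.03, adjusted p = 0.0126).

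Markers of other cells that the preparation could hold did not pass as groups over all 6 mice. B cell markers had a median difference of -0.031 over 15 genes (adjusted p = 0.387), myeloid and dendritic cell markers -0.058 over 19 genes (adjusted p = 0.387), DN thymocyte and progenitor markers -0.051 over 9 genes (adjusted p = 0.277) and CD8 SP, NK and gamma-delta T markers 0.008 over 9 genes (adjusted p = 0.562). In the last of these lists Itgae, shared with the Treg list, was higher adjusted over the list alone (limma adjusted p = 0.0263). Erythroid (6 genes), stromal and endothelial (9 genes) and thymic epithelial markers (11 genes) had medians of 0.002, 0.009 and 0.002, with adjusted p of 0.762, 0.708 and 0.708. Without knockout 3 the myeloid and dendritic list passed in the lower direction (median -0.115, adjusted p = 0.00237), without knockout 2 its median was 0.016 (adjusted p = 0.623) and without control 3 it was -0.017 (adjusted p = 0.641). The erythroid median ranged from -0.04 to 0.008 without 1 mouse, and that of the DN list was -0.033 without control 2. Cst3, an abundant transcript of dendritic cells, differed by -0.125 (SE 0.05), and Cd44, high on early progenitors, by -0.141 (SE 0.059), while the other 3 tested Cd44 probes went the other way, at 0.0216 to 0.0855.

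Control 3 differed from the other mice in genes of the sex chromosomes. Xist, the transcript of the inactive X, read 2.116 in control 3 and -0.558 to -0.404 in the other 5 mice. Eif2s3y and Kdm5d, both Y-linked, read -0.834 and -0.749 in control 3, against 1.533 to 1.894 and 0.271 to 0.561 in the other mice. Some genes outside the sex chromosomes also took separate levels in single mice that did not follow genotype. The protease gene Ctsc read 0.8, 0.92 and 1.082 in knockout 1, control 2 and control 3, and -0.605, -0.483 and -0.474 in knockout 2, knockout 3 and control 1.

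**Figure D3:**
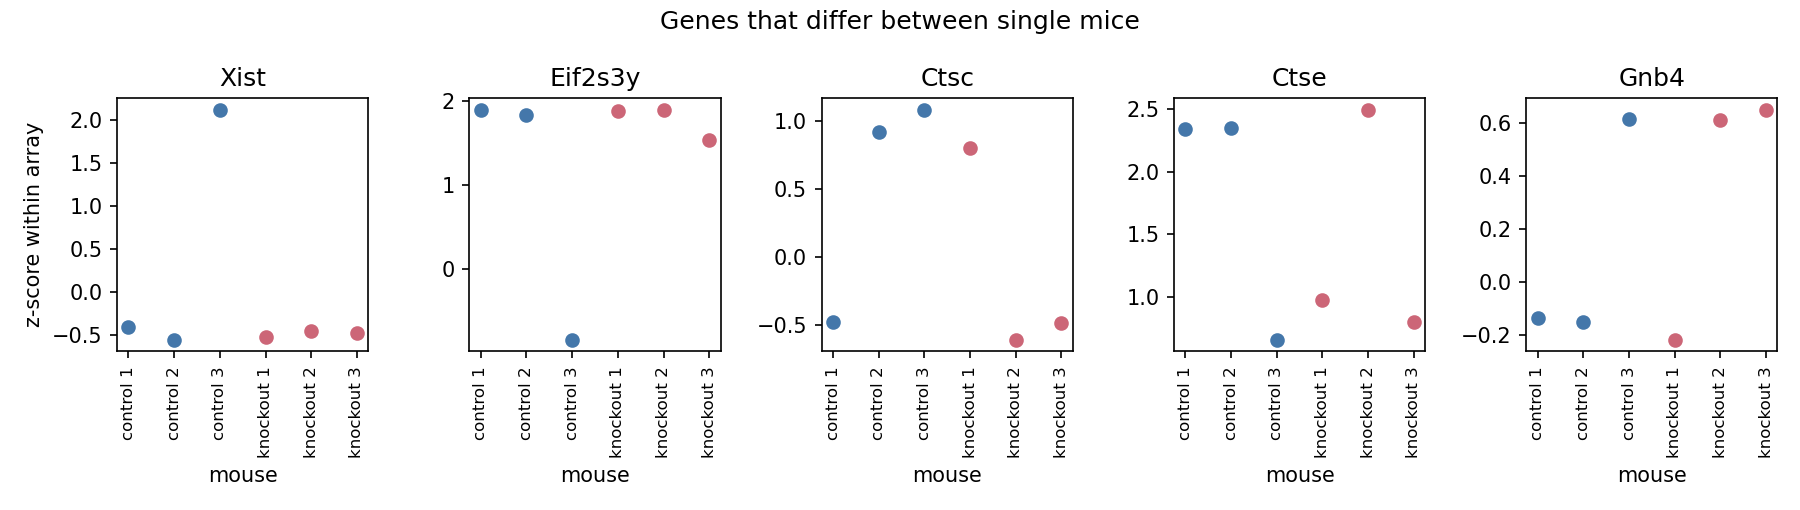
Z-scores (y axis) of Xist, Eif2s3y, Ctsc, Ctse and Gnb4 in each of the 6 mice (x axis; blue control, red knockout). Control 3 stands alone for Xist (2.116) and Eif2s3y (-0.834), and the other genes, chosen after their values were seen, take a low and a high level in mice of both genotypes.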

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

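The alternatives reported here were planned. The stricter filter removes ILMN_1241903 and ILMN_1221264, so it gives no value for them. Klf4 was lower on ILMN_1241903 and past the threshold in all 13 alternatives of the limma fit that give it a value (-0.736 to -0.627, adjusted p 0.000226 to 0.0314). ILMN_1221264 was lower in all 13 of these and past the threshold in 7: without a trend it read -0.376 and did not pass, and 5 of the 6 fits without 1 mouse (-0.425 to -0.336) did not pass, with adjusted p from 0.00608 to 0.264 over the alternatives. ILMN_2999439 ranged from -0.052 to 0.14 without 1 mouse and turned to -0.044 without knockout 2 and -0.052 without control 3. The cause was not tested. In the unequal-variance test per probe no Klf4 probe passed. Probes called higher numbered 1 with robust variance, 1 at an adjusted p under 0.1 and 0 to 1 without 1 mouse (1 without control 3). Probes called lower numbered 0 at the stricter filter, 0 with 1 probe per gene, which keeps the unaffected Klf4 probe, 0 with the unequal-variance test, 1 without a trend and 1 to 4 without 1 mouse (4 without knockout 1, 1 without knockout 3, control 1 or control 2). With the replicate number as a replicate block 2 probes were higher, 1 of them Bach1 (0.501, SE 0.058, adjusted p = 0.0134), and 2 lower, and 5 lists passed. Deviations of mice with the same number correlated at -0.034, 0.167 and 0.035, and not every mouse correlated best with its own number. The value of 0.167 was the highest of all pairs. With 3 mice per genotype these correlations depend on each other, so they cannot settle whether mice of the same number were processed together. Lists past the threshold numbered 0 with an estimated correlation and 5 to 6 without 1 mouse, but only 2 of the 5 main lists were among the 5 without control 3. The Treg list was past the threshold in all 13 alternatives at the preset correlation.

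For genes and lists that were not called, the direction also turned in places, by sign for genes and by the test for lists, whose median can keep its sign. Without a filter it turned for CDK inhibitors (-0.024) and thymic epithelial markers (-0.004), and at the stricter filter for apoptosis regulators (0.001). With deposited scores it turned for CDK inhibitors (-0.024), oxidative phosphorylation (0.013), Rps16 (0.01) and Thy1 (0.046), and with median centring for Cd8a (0.001), oxidative phosphorylation (0.015), Rps16 (0.012) and Thy1 (0.048). Array weights turned Uty (-0.006) and the replicate block CDK inhibitors (-0.032). Ranges over the fits without 1 mouse follow for results that turned there. Among genes these were Ccl5 (-0.023 to 0.118, turned without control 3), Cd4 (-0.028 to 0.096, turned without knockout 1 or knockout 2 or control 1) and Cd8a (-0.026 to 0.006, turned without knockout 2 or control 2). Further genes were Eif2s3y (-0.096 to 1.27, turned without control 3), Epor (-0.003 to 0.011, turned without knockout 1) and Il17a (-0.017 to 0.074, turned without knockout 1). Also turning were Il7r (-0.02 to 0.107, turned without knockout 3), Kdm5d (-0.187 to 0.471, turned without control 3) and Klf2 (-0.021 to 0.105, turned without knockout 2). The last genes were S1pr1 (-0.063 to 0.008, turned without knockout 2 or control 1), Tagln (-0.033 to 0.003, turned without knockout 1) and Uty (-0.049 to 0.117, turned without control 3). Among lists these were apoptosis regulators (-0.005 to 0.007, turned without knockout 2), B cell markers (-0.049 to -0.001, turned without knockout 2) and CD8 SP, NK and gamma-delta T markers (-0.049 to 0.029, turned without knockout 3). Further lists were CDK inhibitors and antiproliferative genes (-0.047 to -0.003, turned without control 1 or control 2), cytosolic ribosomal proteins (-0.026 to 0.012, turned without control 3) and glycolysis (-0.03 to 0.026, turned without control 3). Lists of the same kind were KLF family (-0.021 to 0.035, turned without knockout 2 or control 3), myeloid and dendritic cell markers (-0.115 to 0.016, turned without knockout 2) and oxidative phosphorylation (-0.03 to 0.005, turned without knockout 1 or control 1 or control 2). The last lists were stromal and endothelial markers (-0.01 to 0.03, turned without knockout 3 or control 1), TCR signal response and positive selection (-0.024 to 0, turned without knockout 1) and thymic epithelial markers (-0.01 to 0.011, turned without knockout 2). The cause was not tested. A threshold of 1.5-fold and an offset before the logarithm were not run, since the scores have no fold or linear scale, and robust variance is no option of camera. Signal over background is unknown here.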

Other observations

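The tests on other splits, on gene order and on the role of control 3 were chosen after the results were seen. The fits without 1 mouse and with an estimated correlation, which the last of these reads, were planned, and the test with 1 gene per symbol stem was set before its own result was seen. Several genes took 2 separate levels among the mice without following genotype. Ctse, an aspartic protease gene, read 0.977, 0.801 and 0.655 in knockout 1, knockout 3 and control 3, and 2.496, 2.337 and 2.348 in knockout 2, control 1 and control 2. Gnb4, a G-protein subunit gene, read -0.219, -0.135 and -0.15 in knockout 1, control 1 and control 2, and 0.609, 0.65 and 0.613 in the other mice, and Nudt6, Mgst2, Cd1d1 and Rps3a1 parted the same mice. Pclaf, a replication-associated gene, read 2.383, 2.228 and 2.288 in those 3 mice and 1.658, 1.659 and 1.509 in the others. Lyz2, the lysozyme gene of myeloid cells, read 1.255, 1.242 and 1.384 in knockout 3, control 1 and control 3, and 0.835, 0.691 and 0.827 in the others. The median of the myeloid and dendritic list parted the same mice, at -0.046, -0.079 and -0.039 against -0.131, -0.244 and -0.131. Whether the share of myeloid cells varied between mice was not tested. The genes of this paragraph are among those past the threshold when the 6 mice are split otherwise, and were chosen after their values were seen.

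There are 10 splits of the 6 mice into 3 and 3, too few for a share under 0.05. The real split gave 0 probes higher and 2 lower, and the highest count in one direction among the other splits was 7. All 10 splits reached the real count of higher probes, but any split reaches 0, so this comparison carries no information. As many as the real count of lower probes were given by 3 splits. The real split gave 5 lists and the highest other 8, with 5 splits at 5 or more. It gave 1360 probes at an unadjusted p under 0.05 and the highest other 986, so 1 split, the real one, reached that count. The split of knockout 1, control 1 and control 2 against the rest called 11 probes and that of knockout 1, control 2 and control 3 against the rest called 6, against 2 in the real split, which points to a structure of the samples.

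A candidate explanation is that the mice differ in inherited genomic segments, as in a line not fully bred to one strain. In 5 of the 9 other splits the 100 genes with the smallest p crowded into a stretch of 100 neighbouring genes more than shuffled gene order gave (adjusted p under 0.05). The split that called Lyz2 was not among them (adjusted p = 0.22 from the shuffles). Rbl2 and Zfp868, named above between the genotypes, were among the leading genes in the fullest stretches of such splits. Other named genes can lie within these stretches without being leading genes of those splits, and this was not examined. The fullest stretch held 12 genes, with Gm5796, Pxk, Vcl and Vdac2, where shuffling gave a median of 5 (permutation p = 1e-04, the smallest that 10000 shuffles can give). Families of similar neighbouring genes read by shared probes do not account for all of it, since 2 of the splits kept such a stretch with 1 gene per symbol stem, while 3 moved to an adjusted p of 0.05, 1 of them from 9 to 7 genes (adjusted p 0.0013 before) and the other 2 with 7 genes both times (adjusted p 0.047 before). Shared regulation of neighbours and sequence differences under the probes stay open and were not tested.

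A segment inherited together with the genotype could lie behind some of the genes with the smallest p between the genotypes, and this cannot be told apart here. Their 100 leading genes held at most 5 in such a stretch, the median of shuffled order (permutation p = 0.62). In all, 21 combinations of ranking (by p, by size of the difference, or the 24 named genes), number of leading genes and stretch length were tried, with permutation p from 0.0075 to 0.93, unadjusted for the number tried. With stretches of 200 genes 5 of 7 were under 0.05, and with shorter stretches 0 of 14, so the outcome depends on the stretch length, and the first combination tried is the one tested here. At a stretch of 200 the 24 named genes held 5, where shuffling gave a median of 3 (permutation p = 0.014).

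Some of the lists called between the genotypes may rest on control 3, which differed in Xist and Y-linked genes as a mouse of the other sex would. Without control 3 the interferon-stimulated list had an adjusted p of 0.0705 (median 0.029, from 0.071) and the DP thymocyte programme one of 0.641 (median -0.032, from -0.053), and both stayed past the threshold without each of the other mice, which is consistent with a part played by that mouse. The fit without it also has fewer samples. The deposited scores of control 3 also had the highest upper quartile, 0.517 against 0.436 to 0.477 in the other mice. The G1/S list had an adjusted p of 0.37 without control 3, but also lost its call without knockout 1. The stress list (adjusted p = 1.81e-06) and the Treg list (adjusted p = 0.00508) stayed past the threshold without control 3. In both lists control 3 was the control furthest in the direction of the knockouts' shift, with medians of 0.897 and 0.202. Without it the stress median was -0.101 (from -0.075) and the Treg median stayed at 0.072. These values argue against control 3 as the source of the shift in these lists. With an estimated correlation 0 lists passed, which at 4 residual degrees of freedom cannot decide whether a list is shifted. Sex is one of several ways in which control 3 can differ. The source of the shifts in the called lists stays open.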
